A study of Rattus norvegicus with 6 samples.

How the data were processed

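RNA was sequenced from 6 cultures of INS-1, an insulin-secreting cell line derived from a rat insulinoma. Per the labels, 3 libraries came from cells named INS-MOCK and 3 from cells named INS-SMA, in which lentivirus carried a gene for alpha smooth muscle actin (α-SMA, encoded by ACTA2). The series describes the 3 libraries of each group as biological replicates. The labels give INS-MOCK the genotype wild type and do not say whether those cells received a lentivirus.

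The authors deposited 1 table of raw counts, whole numbers per transcript row, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, HISAT2, HISAT and DESeq2 were used, and the genome builds hg19 and rn6 are named without their roles. The counting program, its strand setting and the gene annotation are not given in the sources used here. The deposited table holds 101905 rows. Of these, 35604 name a gene, through Ensembl rat identifiers or 1 human ACTA2 sequence of 1152 bases. The other 66301 rows carry assembled transcript identifiers (MSTRG) with no gene, and they held 32.7% to 36.7% of the counts of a library. They were left out of library sizes and tests, and reads of a known gene that fell in such a row are missing from that gene's value. Many members of the fixed gene lists were lost in this way or by the count filter. For example, Gapdh was not among the named rows, and Vim and Ldha were below the filter. Of 18 other islet cell genes 10 were among the named rows and 6 were tested. For 20 immune and endothelial markers these numbers were 13 and 6, for 20 acinar and duct markers 14 and 8, and for 24 matrix markers 23 and 10. All 24 unfolded protein and stress genes and all 23 oxidative phosphorylation genes were tested. A low value in this table is therefore not proof of low expression. Gene coordinates are those of the deposited table. The only rat build that the processing notes name is rn6.

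Counts were summed over the rows of each gene, which gave 21553 genes, 6254 of them from several rows. edgeR's filterByExpr kept 13363 genes. Library sizes were normalised with TMM factors, and groups were compared with edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest) on all 6 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Normalised counts are CPM on the TMM-scaled library sizes, given as mean ± SD over 3 libraries. Where a gene had no counts in a group, its fold is a lower bound against a floor of 3 counts per library. Where a group had 1 to 3 counts in all, the ratio is given with an exact 95% binomial interval. Floors and such intervals cover counting error only.

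The 23 gene lists were fixed before the data were examined. Each was compared with all other tested genes with limma's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with adjustment over the 23 lists. The same was done with an estimated correlation, and fry tested each list by itself. Where a symbol had several genes (156 symbols), the one with the highest mean count was used. The rule for named genes was also set then. It took Acta2, Ins1, Ins2, Pdx1 and Mafa, and the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold, with ACTA2 left out. These 12 needed a mean of at least 5 CPM and groups that did not overlap. It also took, from each list with a member past the threshold, the 2 members with the smallest adjusted p, or 4 for the lists of beta cell transcription factors, insulin and granule, exocytosis, smooth muscle, and matrix genes. All other genes named in the text were chosen after their values were seen. Some genes that the rule takes are not reported here.

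The libraries held 24719503 to 39608609 counts, of which 15851326 to 25075476 lay in tested genes. A floor of 3 counts corresponds to 0.117 to 0.180 CPM. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 42.7 to 55.6), so none was counted as a duplicate. On simulated counts for the 13363 genes of INS-SMA against INS-MOCK, with 200 genes changed, the edgeR test recovered 21% of genes changed by 1 log2 unit and 61% of those changed by 2. It called 3 unchanged genes. With DESeq2 the recovered shares were 64% and 89%. The changed genes all had a mean of at least 5 CPM and were few beside the 7359 genes that passed in the data. The adjustment for multiple tests was therefore stricter than in the data, and these shares do not give the power of the real comparison. In a second simulation camera found the 1 shifted list of 23 and called 0 of the others. Its genes were drawn independently of each other, so it could not test the preset correlation of 0.01. In the data the estimated correlation reached 0.45, in the interferon list.

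Alternatives set before the data were examined were DESeq2's Wald test, RLE and upper-quartile factors, no factors, no or a stricter low-count filter (1 CPM in 3 libraries), transcript rows instead of gene sums, the highest row of each gene, ACTA2 left out, the replicate number as a block, each library left out in turn, and stricter thresholds. A gene's value given as transcript rows is that of its most abundant tested row, fitted beside all other rows. It normally rests on the same row as the setting with the highest row of each gene, so these settings are not separate checks of a gene. Keeping the unnamed rows in the library sizes, leaving out mitochondrial genes, and leaving out unstable genes were added after seeing the data. A gene was called unstable if its CPM plus 1 differed over 8-fold between libraries of 1 group. No genome sequence was used here, so GC content and transcript length were not examined. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.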

Results

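Gene expression was measured by RNA sequencing in INS-1 rat insulinoma cells expressing α-SMA from a lentivirus (INS-SMA, n = 3) and in mock cells (INS-MOCK, n = 3). The INS-MOCK libraries held 34471794 to 37466920 counts and the INS-SMA libraries 24719503 to 39608609. The series compared both groups to find genes whose expression differs when INS-1 cells overexpress α-SMA. Alpha smooth muscle actin is an actin of smooth muscle cells and myofibroblasts.

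The overexpressed gene was examined first. The human ACTA2 sequence was at 51072 ± 6224 CPM in INS-SMA (SD, n = 3) and at 5.78 ± 1.27 CPM in INS-MOCK, a log2 fold change of 13.11 (SE 0.28, edgeR adjusted p = 4.39e-06). It held 941093, 1141322 and 1139159 counts in the INS-SMA libraries and 135, 103 and 167 in the INS-MOCK libraries. In INS-SMA it made up 5.27% ± 0.69 of the counts in named genes. The rat gene Acta2 (chromosome 1, 252537615 to 252550394, minus strand) had 0 counts in each INS-MOCK library and 13, 17 and 22 in the INS-SMA libraries, so it was at least 6.25-fold higher. Reads from the human sequence and from rat actin genes can be hard to tell apart, and the values of rat Acta2, Acta1 and Actg1 are uncertain for that reason.

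Of 13363 tested genes, 7359 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3753 higher and 3606 lower in INS-SMA. At least 2-fold changes were seen for 2078 of the higher and 1667 of the lower genes. The median log2 fold change of all tested genes was 0.03. In 65.3% of tested genes the groups did not overlap, where chance gives 10% for 3 against 3. Among abundant genes outside the fixed lists, Txnip, an inhibitor of thioredoxin, rose from 130.6 ± 8.35 to 2283 ± 86.4 CPM. Aen, an apoptosis-enhancing nuclease, rose from 2.70 ± 0.31 to 809.8 ± 18.2 CPM. Enpp2, which encodes the lysophospholipase autotaxin, fell from 2810 ± 93.5 to 118 ± 44.1 CPM.

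**Figure D1:**
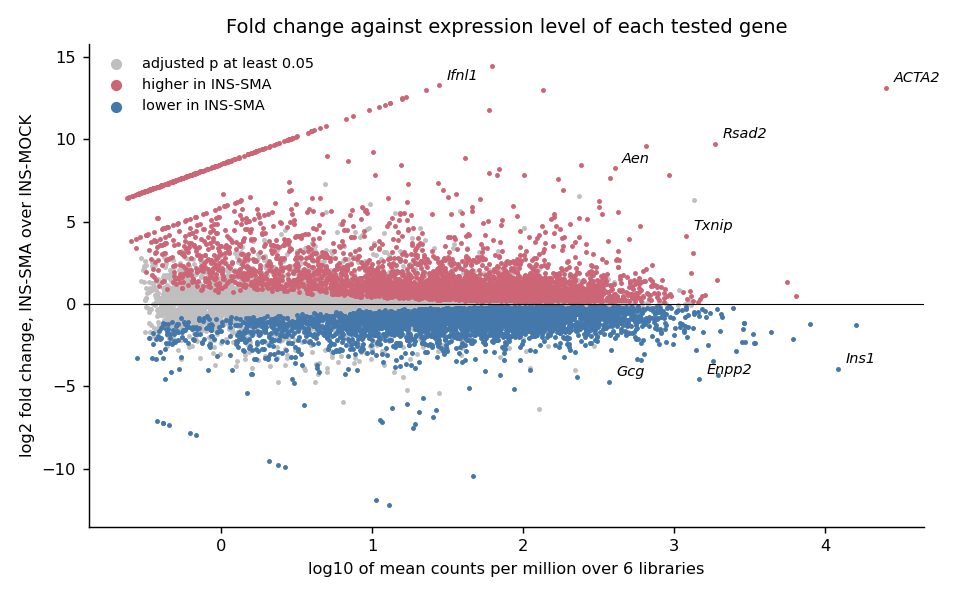
Each point is 1 of the 13363 tested genes, with the log10 of its mean CPM over 6 libraries on the x axis and its log2 fold change (INS-SMA over INS-MOCK) on the y axis, coloured by the edgeR call at an adjusted p of 0.05. Genes with 0 counts in INS-MOCK form the straight upper line, where the plotted fold depends on the prior count; ACTA2 lies at the right with a log2 fold change of 13.11 and Ins1 at -3.93.

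Of the 6 genes with the largest rises by the fixed rule, 5 had 0 counts in INS-MOCK and Gbp5 had 2. The interferon lambda genes Ifnl1 (chromosome 1, 85252103 to 85253635) and Ifnl3 (chromosome 1, 85236243 to 85237775) had 0 counts in INS-MOCK. They reached 55.6 ± 1.16 and 45.4 ± 5.44 CPM in INS-SMA, at least 431-fold and at least 352-fold higher. RGD1305938 was at least 964-fold higher at 124.2 ± 9.03 CPM. The interferon-induced GTPase gene Gbp5 was at 272 ± 7.99 CPM in INS-SMA against those 2 counts, a ratio of 9543 (95% interval 2641 to 78803). Both counts were in INS-MOCK replicate 1. The log2 fold change of Gbp5 was 12.96, and 15.55 without that library. Edil3 was at least 260-fold higher. It varied between INS-SMA libraries (33.5 ± 28.2 CPM), and its adjusted p of 0.0311 in edgeR's test was 0.0569 to 0.086 without any library but INS-SMA replicate 3, and 0.0537 as transcript rows.

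The largest falls by the same rule were in Col6a6, Phactr4, AABR07072184.1, Mtmr6, Arl2bp and LOC103692169. Phactr4 was at 21.4 ± 5.84 CPM in INS-MOCK and had 0 counts in INS-SMA, at least 148-fold lower. Col6a6 was at least 180-fold lower, with 26.1 ± 23.2 CPM in INS-MOCK. Its log2 fold change was -12.19, and -11.30 without INS-MOCK replicate 2. AABR07072184.1 went from 92.6 ± 2.26 to 0.059 ± 0.058 CPM, with a log2 fold change of -10.43 that was -11.50 without INS-SMA replicate 3. LOC103692169 went from 23.3 ± 1.37 to 0.158 ± 0.021 CPM. Mtmr6 (37.1 ± 32.3 CPM in INS-MOCK) and Arl2bp (38.4 ± 32.7 CPM) each had 1 INS-MOCK library near 0. The adjusted p of Mtmr6 was 0.0161 in edgeR's test and 0.053 to 0.0621 without any 1 of the INS-SMA libraries. That of Arl2bp was 0.0212, and 0.0512 to 0.0714 without any library but INS-MOCK replicate 2. The log2 fold change of Arl2bp was -7.29, and -7.91 without INS-SMA replicate 2.

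Genes of insulin production and the secretory granule fell together. Ins1 (chromosome 1, 272799784 to 272800347) went from 22960 ± 895 to 1505 ± 182 CPM, a log2 fold change of -3.93 (SE 0.11, edgeR adjusted p = 6.86e-06). Ins2 (chromosome 1, 215856971 to 215858034) went from 3722 ± 465 to 190 ± 42.9 CPM, a log2 fold change of -4.29 (SE 0.20, adjusted p = 3.07e-05). Ins1 and Ins2 are near-identical copies, so the division of reads between them is uncertain. The proinsulin convertase genes Pcsk1 and Pcsk2 fell, with log2 fold changes of -3.33 and -2.86. The granule zinc transporter gene Slc30a8 (-2.11), the amidating enzyme gene Pam (-2.33), Ptprn (-1.89) and the granin genes Chga (-2.39) and Scg2 (-3.02) fell as well. Of 21 tested members of this list, 16 fell and 0 rose, and the counts were the same when adjusted over the list alone. The list stood below other genes by camera (median log2 fold change -1.89, adjusted p = 7.06e-07; adjusted p = 0.27 with an estimated correlation). Iapp (amylin) and Ica1 did not pass the test, with log2 fold changes of 2.30 (0.52 without INS-SMA replicate 2) and 0.92 (2.68 without INS-MOCK replicate 1). The adjusted p of Iapp was 0.0979, and 0.0163 with DESeq2 in a range of 0.0163 to 0.286 over the alternatives.

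**Figure D2:**
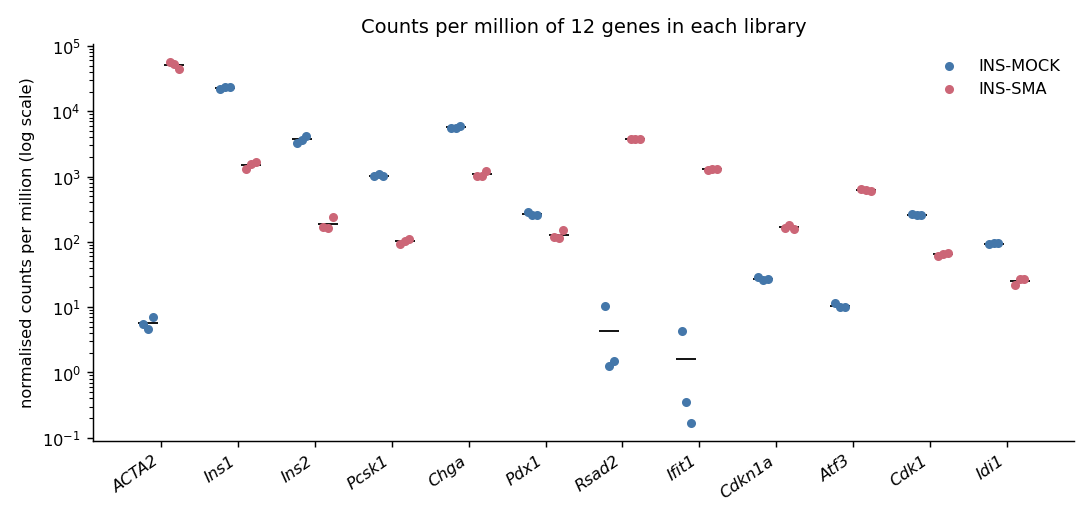
Normalised CPM on a log axis for 12 genes in each of the 3 INS-MOCK and 3 INS-SMA libraries; points are libraries and horizontal lines group means. In all 12 genes the groups do not overlap; Ins1 goes from a mean of 22960 to 1505 CPM, and Rsad2 and Ifit1 are highest in INS-MOCK replicate 1 among the INS-MOCK libraries.

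Several transcription factors of the beta cell fell as well. Pdx1, a master regulator of beta cells, went from 268 ± 17.9 to 128 ± 20.9 CPM, a log2 fold change of -1.06 (SE 0.13, edgeR adjusted p = 9.07e-04). Isl1 (-2.40), Neurod1 (-1.32), Nkx6-1 (-1.37) and St18 (-1.01) fell. Rfx3 rose by 1.28 at an edgeR adjusted p of 0.0486, which was 0.0696 to 0.138 without any library but INS-MOCK replicate 2. It was 0.0503 to 0.109 with no low-count filter, as transcript rows, in its most abundant row, with unnamed rows in the library sizes and without mitochondrial genes. In all, 7 of 16 tested members fell and 2 rose, or 8 and 2 adjusted over the list alone. By camera the list as a whole did not pass the threshold (median -1.03, adjusted p = 0.0678). It passed with no low-count filter (0.00852), without normalisation factors (0.0457), without INS-MOCK replicate 3 (0.0448) and without INS-SMA replicate 2 (0.0451), in a range of 0.00852 to 0.0881 over settings of camera with the preset correlation, and was at 0.44 with an estimated correlation. Mafa varied within both groups (122 ± 84.8 and 38.3 ± 27.0 CPM) and did not pass the test, with a log2 fold change of -1.67 (adjusted p = 0.19; -2.29 without INS-SMA replicate 2). Nkx2-2 had a log2 fold change of -3.22 and an adjusted p of 0.0503. That p was 7.74e-05 without INS-SMA replicate 1, 0.00904 with DESeq2 and 0.0479 to 0.0489 with upper-quartile factors, the strict low-count filter, unnamed rows in the library sizes and mitochondrial genes left out, in a range of 7.74e-05 to 0.101 over the alternatives.

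Among genes of glucose sensing and insulin exocytosis, 8 of 22 tested members fell and 1 rose (2 without INS-SMA replicate 1), with the same counts adjusted over the list alone. The fatty acid receptor gene Ffar1 fell by 2.39 on the log2 scale, and Sytl4 (granuphilin, -2.78) and the exocytosis gene Snap25 (-2.27) fell too. Syt4 was the member that rose, by 0.61. Kcnj11, a subunit of the ATP-sensitive potassium channel, fell by 0.41. The glucose transporter gene Slc2a2 (log2 fold change -0.30) and the sulfonylurea receptor gene Abcc8 (-0.50) did not pass the test. The sign for Slc2a2 turned without INS-MOCK replicate 3 (0.39) or INS-SMA replicate 2 (0.06). Abcc8 passed without INS-SMA replicate 3 (adjusted p = 0.0432, in a range of 0.0432 to 0.817 over the alternatives). The list stood below other genes by camera (median -0.40, adjusted p = 0.032; adjusted p = 0.27 with an estimated correlation).

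Hormone and marker genes of other islet cells were lower as well. Gcg, which encodes glucagon, went from 714.1 ± 30.6 to 27.0 ± 2.88 CPM, a log2 fold change of -4.72 (SE 0.10, edgeR adjusted p = 4.17e-06). Gc (-1.49) and Tm4sf4 (-1.29) also fell. Thus 4 of 6 tested members fell and 0 rose (1 without INS-MOCK replicate 3), with the same counts adjusted over the list alone (camera median -1.23, adjusted p = 0.028; adjusted p = 0.27 with an estimated correlation). With no low-count filter 4 of 10 members fell and the list lost its call (adjusted p = 0.0656, where other settings of camera with the preset correlation gave 0.0198 to 0.0447). Of 12 tested dedifferentiation and progenitor markers, 5 rose (Hes1, Notch1, Cck, Myc and Jag1) and 3 fell (Gast, Sox9 and Pou5f1), or 5 and 4 adjusted over the list alone. Hes1, a Notch target gene, rose from 7.42 ± 1.58 to 52.2 ± 2.68 CPM, and Notch1 from 36.1 ± 0.54 to 114.4 ± 9.94 CPM. The camera test did not pass (adjusted p = 0.57). The adjusted p of Pou5f1 was 0.0429, and 0.0699 to 0.126 without any library but INS-SMA replicate 2. It was 0.0529 to 0.085 without normalisation factors, with no low-count filter, as transcript rows and in its most abundant row. Of 12 tested genes that beta cells normally keep low ("disallowed" genes), 6 fell, among them Mgst1 (-1.96) and Oat (-1.36), and Cat (0.81) and Lmo4 (2.42) rose (camera adjusted p = 0.41). These counts were 6 and 2 also when adjusted over the list alone.

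Interferon-response genes rose, with a median log2 fold change of 4.59 (4.40 with genes at 0 in INS-MOCK set to their bound). Rsad2 (viperin) went from 4.39 ± 5.22 to 3748 ± 57.0 CPM, Ifit1 from 1.64 ± 2.38 to 1295 ± 19.8 CPM and Isg15 from 3.08 ± 2.16 to 366 ± 68.7 CPM. The chemokine gene Cxcl10 rose by 7.66 on the log2 scale (SE 0.13, edgeR adjusted p = 2.99e-06) and B2m by 2.37. Of 23 tested members 16 rose and 0 fell (1 without INS-MOCK replicate 2), with the same counts adjusted over the list alone (camera adjusted p = 1.15e-06; adjusted p = 0.33 with an estimated correlation). INS-MOCK replicate 1 had more of these transcripts than the other INS-MOCK libraries, with 252 counts of Rsad2 against 28 and 35. Without it the median of the list was 7.67 and 21 of 24 members rose. The log2 fold change then went from 9.73 to 11.41 for Rsad2, from 9.61 to 12.24 for Ifit1 and from 6.89 to 7.64 for Isg15. Among the members 9 were unstable between libraries of a group, and without them 13 of 14 rose.

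Genes of NF-kappaB signalling and inflammation rose too. Nfkbia, which encodes an inhibitor of NF-kappaB and is itself a target, went from 29.9 ± 0.44 to 161 ± 8.92 CPM. Icam1, an adhesion molecule, went from 0.701 ± 0.20 to 63.3 ± 2.23 CPM. The cytokine genes Tnf and Cxcl1 had 0 counts in INS-MOCK and were at least 42.7-fold and at least 44.1-fold higher. Of 16 tested members 11 rose and 0 fell (1 without INS-MOCK replicate 3), with the same counts adjusted over the list alone. The list median was 3.79, or 3.21 with genes at 0 set to their bound, and it was 3.13 without INS-SMA replicate 3 and 5.02 with no low-count filter (camera adjusted p = 2.53e-04; adjusted p = 0.27 with an estimated correlation). Markers of immune and endothelial cells were not raised as a list (camera adjusted p = 0.51). Of 6 tested members, Ptprc (CD45) rose, from 0 counts to 1.52 ± 0.37 CPM, at least 11.8-fold, and 0 fell; adjusted over the list alone the counts were also 1 and 0. Without INS-MOCK replicate 2, 3 members rose, and without INS-SMA replicate 1, 2 rose.

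**Figure D3:**
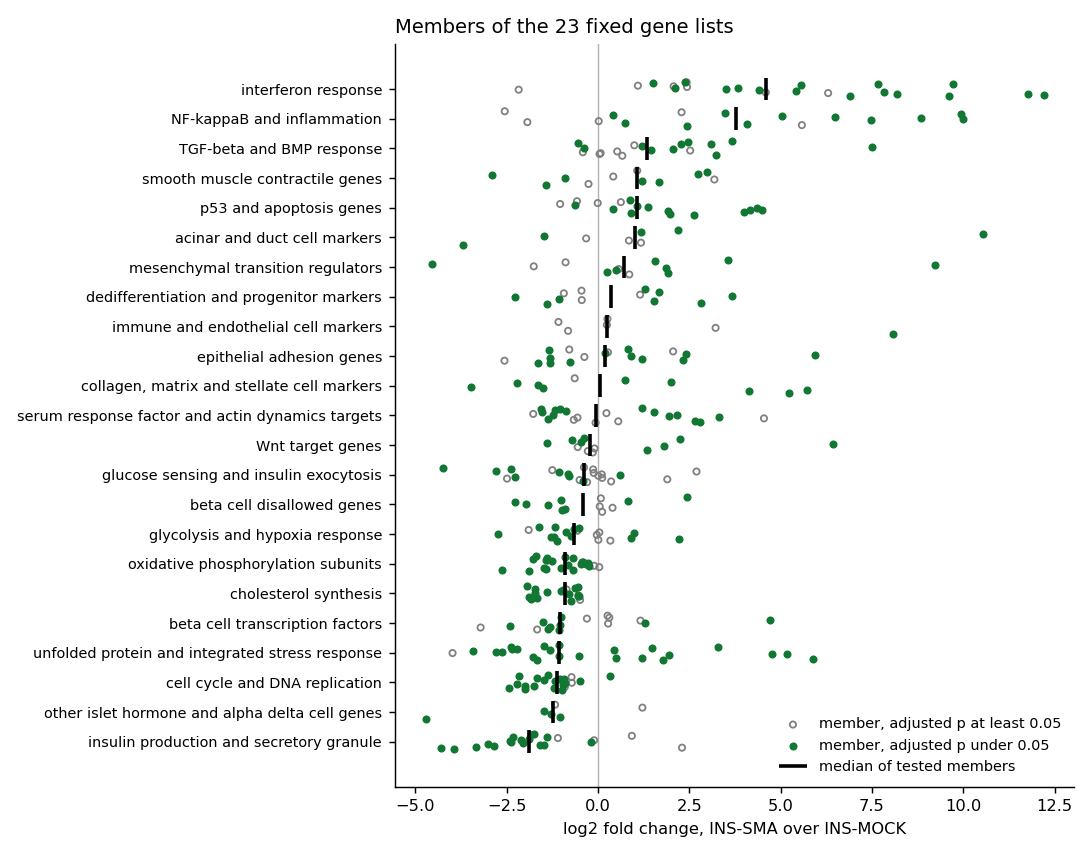
Log2 fold changes (INS-SMA over INS-MOCK, x axis) of the tested members of the 23 gene lists fixed before the data were examined (y axis), with filled points for members past an edgeR adjusted p of 0.05 and black bars for list medians. The interferon list has the highest median (4.59) and the insulin and granule list the lowest (-1.89).

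p53 target and apoptosis genes rose. Cdkn1a (p21), which halts the cell cycle, went from 27.2 ± 1.22 to 167 ± 12.3 CPM, and Phlda3 rose by 4.35 on the log2 scale. Ccng1 went from 550.2 ± 20.9 to 2056 ± 73.1 CPM. The p53 ubiquitin ligase gene Mdm2 rose by 1.96 and the death receptor gene Fas by 4.16 on the log2 scale. Of 17 tested members 12 rose and 1 fell (2 without INS-SMA replicate 3), with the same counts adjusted over the list alone (camera median 1.07, adjusted p = 0.0018; adjusted p = 0.27 with an estimated correlation). Cell cycle and DNA replication genes fell. Cdk1 went from 259 ± 6.12 to 64.7 ± 3.87 CPM and Aurkb from 108.8 ± 3.39 to 23.4 ± 1.25 CPM, and Ccna2 (-2.44) and Top2a (-1.99) fell. Of 22 tested members 18 fell and 1, Tyms (0.33; 0.31 as transcript rows, where its adjusted p of 0.0559 was the highest of its alternatives), rose, with the same counts adjusted over the list alone (median -1.11, adjusted p = 7.06e-07; adjusted p = 0.27 with an estimated correlation). Mki67 fell by 0.98 in the gene sum, but its most abundant transcript row had a log2 fold change of 1.81. The call for Top2a was lost in its most abundant row, where the log2 fold change was -3.57 (adjusted p = 0.331), and as transcript rows (-3.65, 0.391, the highest of its alternatives).

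Of 24 members of the list of unfolded protein and integrated stress response genes, 10 rose and 13 fell, or 10 and 14 adjusted over the list alone, and camera gave an adjusted p of 0.51. Among the members that fell were Hspa5 (BiP, a chaperone of the endoplasmic reticulum), from 2373 ± 77.5 to 739 ± 43.3 CPM, Calr (-2.38) and Pdia4 (-2.64). Among those that rose were Trib3, from 42.6 ± 0.86 to 1147 ± 83.3 CPM, the transcription factor gene Atf3, from 10.6 ± 1.00 to 630 ± 24.0 CPM, Chac1 (5.17) and Ddit3 (1.78).

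Genes of energy and lipid metabolism were lower. Of 23 nuclear genes for oxidative phosphorylation, 21 fell and 0 rose (median -0.90, camera adjusted p = 7.06e-07; adjusted p = 0.27 with an estimated correlation), with Cox7b at -1.78 and Cycs, which encodes cytochrome c, at -1.70. Of 18 tested cholesterol synthesis genes, 16 fell and 0 rose (median -0.91, camera adjusted p = 1.08e-06; adjusted p = 0.27 with an estimated correlation). Sqle went from 197 ± 3.43 to 62.4 ± 5.32 CPM and the regulator gene Srebf2 fell by 0.95. Both pairs of counts were the same adjusted over the list alone. Of 19 tested glycolysis and hypoxia genes, 10 fell, among them Aldoa (-1.20), and 3 rose, namely Pfkfb3 (2.22), Pdk1 (0.99) and Pfkfb4 (0.90). Adjusted over the list alone, 11 fell and 3 rose (median -0.67, camera adjusted p = 0.028; adjusted p = 0.33 with an estimated correlation). The adjusted p of Pfkfb4 was 0.0268, and 0.0555 to 0.0856 without any library but INS-SMA replicate 3; its most abundant row had a log2 fold change of -0.07 (adjusted p = 0.972), and it was at -0.16 (0.956) as transcript rows. Genes encoded by mitochondrial DNA took 7.84% ± 0.465 of the counts in named genes in INS-MOCK and 3.67% ± 0.155 in INS-SMA (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

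Smooth muscle, actin and matrix genes changed in both directions. Of 11 tested smooth muscle contractile genes, 4 rose (Ldb3, Pln, Myh11 and Cald1) and 3 fell (Synpo2, Acta1 and Tpm1), or 5 and 3 adjusted over the list alone (camera adjusted p = 0.78). Ldb3 rose from 2.08 ± 0.49 to 13.8 ± 1.11 CPM, whereas Synpo2 fell from 387.5 ± 5.47 to 52.2 ± 11.4 CPM, as did Tpm1 (-0.91) and Acta1 (-1.41; -1.98 in its most abundant row, adjusted p = 0.0646, and -2.06 as transcript rows, 0.0863, the highest of its alternatives). Myh11 was at 1.21 (adjusted p = 0.0379, and 0.0656 to 0.108 without any library but INS-MOCK replicate 2, 0.0588 with no low-count filter and 0.093 as transcript rows). Cald1 was at 1.66 (adjusted p = 0.0284, and 0.0545 to 0.091 without INS-MOCK replicate 1 or 3 or INS-SMA replicate 2 or 3, 0.0627 with no low-count filter and 0.0539 as transcript rows). The smooth muscle marker Tagln was at -0.26 and did not pass the test.

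Among 21 tested serum response factor and actin dynamics genes, 7 rose and 7 fell, or 8 and 7 adjusted over the list alone. Egr1 rose by 2.78, and Actb, which encodes beta-actin, went from 1708 ± 21.2 to 665.1 ± 25.7 CPM (camera adjusted p = 0.89). Actg1 did not pass the test, with a log2 fold change of 4.54 (0.14 without INS-SMA replicate 1). The median of this list was -0.07 (0.03 without normalisation factors) while its mean was 0.43 and its test pointed upward, or downward without INS-MOCK replicate 3. Of 10 tested matrix and stellate cell markers, 5 rose and 4 fell, also when adjusted over the list alone (median 0.04, camera adjusted p = 0.90). With no low-count filter 7 of 23 members rose and 4 fell, and the median was 1.99 (camera adjusted p = 0.59). Fn1 (fibronectin) fell from 3335 ± 112 to 301 ± 31.4 CPM and Postn from 15.6 ± 0.47 to 4.98 ± 0.77 CPM. Col6a2 fell from 15.3 ± 1.19 to 5.41 ± 0.652 CPM. Thy1 fell, with a log2 fold change of -2.23 that was -3.02 without INS-SMA replicate 3, and its adjusted p of 0.0175 was 0.0533 without INS-SMA replicate 2. Col5a2 rose from 0.274 ± 0.12 to 14.6 ± 1.47 CPM, Ngfr by 0.72, Col4a1 by 4.12, Timp1 by 2.00 and Col3a1 by 5.22 (5.86 without INS-MOCK replicate 1).

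Genes of TGF-beta and BMP signalling rose more often than they fell. The inhibitory SMAD gene Smad7 went from 20.1 ± 0.43 to 189 ± 5.14 CPM and the early response gene Klf10 from 281 ± 8.62 to 2411 ± 44.3 CPM. Of 18 tested members 9 rose and 2 fell, Ltbp3 (-0.54) and Tgfbi (-0.38), with the same counts adjusted over the list alone (median 1.33, camera adjusted p = 0.0069; adjusted p = 0.27 with an estimated correlation). Of 12 tested mesenchymal transition regulators 7 rose, among them Tgfb2 (1.57) and the receptor kinase gene Axl. Axl had 2 counts in INS-MOCK and 20.2 ± 0.55 CPM in INS-SMA, a ratio of 704 (95% interval 195 to 5820). Both counts were in INS-MOCK replicate 1, and the log2 fold change of Axl, 9.21, was 11.80 without it. The member that fell was Itgav, whose log2 fold change of -4.55 was -2.78 without INS-MOCK replicate 3. Its adjusted p of 0.0161 was 0.0528 to 0.0604 without any 1 of the INS-SMA libraries. Counts of 7 and 1 held adjusted over the list alone, and camera gave an adjusted p of 0.0678, and 0.023 without INS-MOCK replicate 1.

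Of 17 tested epithelial adhesion genes 7 rose and 5 fell, also adjusted over the list alone, with Cdh1 (E-cadherin) at -1.32 and Jup (plakoglobin) at -1.35 (camera adjusted p = 0.90). The call for Jup was lost in its most abundant row, where the log2 fold change was -1.27 (adjusted p = 0.216), and as transcript rows (-1.35, 0.238, the highest of its alternatives). Epcam, Cldn7 and Krt7 were the other members that fell. Cldn7 (adjusted p = 0.0336) lost its call without any library but INS-MOCK replicate 1 (0.0558 to 0.109), with no low-count filter (0.0709) and as transcript rows (0.0563). Krt7 (-0.75, adjusted p = 0.0151) lost its call without INS-MOCK replicate 2 (0.0501), in its most abundant row (-0.44, 0.221) and as transcript rows (-0.52, 0.251, the highest of its alternatives). Of 12 tested Wnt target genes 4 rose (Rnf43, Tnfrsf19, Tcf7 and Notum) and 4 fell (Wif1, Apcdd1, Fzd7 and Nkd2), also adjusted over the list alone, with Wif1 at -1.39 and Rnf43 at 1.79. Tcf7 (adjusted p = 0.0495) lost its call without any library but INS-MOCK replicate 3 (0.0838 to 0.143). It also lost it with upper-quartile factors, with no low-count filter, as transcript rows, in its most abundant row, with unnamed rows in the library sizes and without mitochondrial genes (0.0531 to 0.0922). Nkd2 (0.0297) lost it without any library but INS-SMA replicate 3 (0.0532 to 0.0844), without normalisation factors (0.0763), with no low-count filter (0.058), as transcript rows (-0.05, 0.959) and in its most abundant row (0.03, 0.966). Their median was -0.21 (0.43 with no low-count filter), their mean 0.65 and the camera adjusted p 0.90. Of 8 tested acinar and duct markers 3 rose (Cftr, Muc1 and Car2; 5 without INS-MOCK replicate 2) and 2 fell, among them Bhlha15, also adjusted over the list alone (camera adjusted p = 0.45). Cftr had 0 counts in INS-MOCK and was at least 64.5-fold higher.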

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

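All tests in this part were chosen after the results were seen. Counts that name no gene, which the comparisons leave out, made up 36.2% ± 0.477 of an INS-SMA library and 32.8% ± 0.167 of an INS-MOCK library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Of 14675 assembled loci without a gene name that were tested beside the named genes, 7049 passed an edgeR adjusted p of 0.05, 3914 higher and 3135 lower in INS-SMA.

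The 6 libraries can be split into 3 and 3 in 10 ways. For the count of genes, 1 split of the 10, the real one, gave as many as 7359, and the highest of the others was 0 genes with edgeR's test (199 at an unadjusted p under 0.05, and 48 adjusted with DESeq2). For the count of gene lists, 1 split, again the real one, gave as many as 11, and the highest of the others gave 8. With 10 splits a share under 0.05 cannot be reached. Every other split also puts libraries of both groups on both sides, so the difference between groups becomes spread within a side. Their low gene counts follow from that mixing. For the lists, part of the group difference stays between the sides. The other splits therefore do not show what chance alone would give.

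The rise of interferon and NF-kappaB genes in INS-SMA was weighed first. Immune cells mixed into the INS-SMA cultures would bring their own transcripts. The 7 immune markers among the named genes summed to 4.06 CPM in INS-SMA (1.71 in INS-MOCK), which is 0.108% of the level of Rsad2. Rsad2 is itself strongly raised, so this ratio bears only on immune cells as the direct source of its transcripts. It cannot exclude a few such cells acting on the INS-1 cells. Ptprc had 0 counts in each INS-MOCK library and 31, 34 and 29 in INS-SMA. Adgre1 went from 0, 7 and 0 to 21, 21 and 20 counts. Cd68 had a lower mean in INS-SMA, but its counts overlapped (3, 20 and 16 against 5, 3 and 13). Aif1 was lower by only 2 counts, both in INS-MOCK replicate 3. Csf1r (0.92 to 1.09 CPM), Cd14 (0 to 0.026 CPM) and Fcer1g (0.086 to 0.109 CPM) had slightly higher means in INS-SMA. Delivery by lentivirus rather than the expressed protein stays open, because the labels describe 0 groups that carry a lentivirus without ACTA2. Whether the rise comes from α-SMA or from the vector cannot be told apart here.

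The fall of insulin and secretory granule genes was weighed next. A move of reads to a single locus without a gene name does not account for the fall of Ins1, since the largest gain of such a locus was 1844 CPM, or 8.59% of the fall of Ins1 (21455 CPM). That gain was also below the falls of Ins2 (3532 CPM), Pcsk2 (3884 CPM) and Chga (4584 CPM). It exceeded the falls of the other members, such as Chgb (1342 CPM) and Pam (1185 CPM), so for those a single unnamed locus stays open. Reads spread over several such loci stay open, because the loci that rose gained 4.31 times what the 16 members that fell lost (41470 CPM), and all such loci together gained 46745 CPM net, 1.13 times as much. The highest share of ACTA2 in a library (5.93%) can shift other genes by at most -0.0881 on the log2 scale, so counts taken by the transgene do not account for a list median of -1.89 (-2.10 to -1.84 over left-out libraries); all 16 members fell by more than that shift, 15 of them by over 4 times as much, and Scg5 (-0.20) by the least. The labels describe 0 groups with a lentivirus and no ACTA2, so the vector and α-SMA cannot be told apart for this pattern either.

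Some named genes had counts near 0 in 1 library of a group and high counts in the others, such as Arl2bp and Mtmr6. At 0 in 1 INS-MOCK library and at 5 CPM or more in the other 2 were 64 genes (60 in INS-SMA). Of genes with several rows, 3.00% were unstable after summing, against 18.6% of their single rows, and of genes with 1 row 8.69% were unstable. Neither a technical nor a biological explanation of the genes that stayed unstable was tested.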

How the results depend on the processing

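Unnamed rows in library sizes, leaving out unstable genes and leaving out mitochondrial genes were alternatives chosen after seeing the data, as were 4 further gene lists. The count of genes past the threshold was 7359, and 5822 to 8300 under the other tests, scalings, filters, row choices and added alternatives. The setting with transcript rows entered that range with a count of rows (7054), which belonged to 5776 genes. Of the 8300 genes called by DESeq2, 7349 were among the 7359. Leaving out 1 library gave 6771 to 7001 genes, and an adjusted p under 0.01 gave 5672. A change of at least 2-fold left 3745 genes, 2078 higher and 1667 lower, because that threshold is stricter by construction. Without normalisation factors 55.9% of the called genes were higher, against 51.0%. The share was 49.4% with unnamed rows in the library sizes, 49.2% without mitochondrial genes and 49.9% with the replicate block. Which direction held the small majority therefore depended on the setting. As transcript rows, 246 genes had rows past the threshold in both directions.

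Of 23 lists, 11 passed. With an estimated correlation 0 did by camera (3 at an unadjusted p under 0.05), with fry 21 and with fry in either direction 23; fry does not compare a list with other genes. Among the named genes, 2832 results kept their direction and their side of the threshold, 106 fell below it, 9 rose past it and 7 reversed. Among the lists 390 kept both, 12 fell below, 24 rose past it and 11 turned in the direction of the test, none of them from a list that passed. These were matrix markers without factors (median 0.13), without INS-SMA replicate 3 and with fry (0.043), smooth muscle genes with the strict filter (0.43), epithelial genes without INS-MOCK replicate 2 or INS-SMA replicate 3 and with fry (0.20), Wnt targets without INS-MOCK replicate 3 and with fry (-0.21), serum response factor genes without INS-MOCK replicate 3, and the unfolded protein list with fry (-1.07). Over left-out libraries the medians ran from 0.27 to 1.35 (matrix), 0.012 to 0.50 (epithelial), -0.22 to -0.078 (Wnt) and -0.25 to 0.045 (serum response factor). In 8 more results, in 4 lists, the median changed sign but not the test.

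The log2 fold change of Mki67 (-0.98) was 1.73 in transcript rows and 1.81 in its highest row, and that of Pfkfb4 (0.90) was -0.16 and -0.072. In both settings the value is that of the gene's most abundant row, so they are not separate checks. Nkd2 (-0.38) was at 0.032 in its highest row. Over left-out libraries Slc2a2 ran from -1.17 to 0.39. The cause was not tested.

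With the replicate number as a block, 6294 genes passed. Over all tested genes, libraries of the same number did not deviate together (residual r of -0.03, -0.01 and -0.03). That does not exclude a shared day or batch for single genes, and the labels do not say what the numbers mark. Under the block Mafa passed (adjusted p = 0.0168, with alternatives up to 0.378). Acta2 (0.0697), Ptprc, Notum, Mtmr6, Arl2bp, Myh11, Cald1, Itgav, Pfkfb4, Nkd2, Cldn7, Krt7, Pou5f1 and Tcf7 did not (0.0516 to 0.145).

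Depth limits genes near the floor, at 0.117 to 0.180 CPM per library. In the first simulation 21% of genes changed by 1 log2 unit were recovered. It held only 200 changed genes, all with a mean of at least 5 CPM. That share therefore describes neither genes near the floor nor the power of the real comparison.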

Other observations

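The lists in this part were chosen after the data were seen. All 13 messenger RNAs encoded by mitochondrial DNA fell in INS-SMA, with the same count adjusted over the list alone (median log2 fold change -2.15, camera adjusted p = 1.48e-07; adjusted p = 0.146 with an estimated correlation). Mt-co1 went from 22787 ± 1040 to 9512 ± 483 CPM, Mt-nd5 from 5762 ± 616 to 1093 ± 91.4 CPM and Mt-cyb from 9981 ± 488 to 2243 ± 62.8 CPM. Other mitochondrial genes of the deposited table rose, AY172581.24 (MT, 1094 to 2664) by 1.35 and AY172581.9 (MT, 68 to 1025) by 1.45 on the log2 scale. Of 64 tested genes for cytosolic ribosomal proteins, 51 fell and 3 rose (Rpl12, Rplp2 and Rps20), or 52 and 3 adjusted over the list alone (median -0.72, camera adjusted p = 1.36e-09; adjusted p = 0.136 with an estimated correlation).

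Genes for antigen presentation by MHC class I rose. Tap1, a peptide transporter of the endoplasmic reticulum, went from 91.4 ± 31.4 to 473 ± 72.1 CPM, and the immunoproteasome gene Psmb9 from 26.8 ± 2.73 to 92.4 ± 6.46 CPM. Of 20 tested members 15 rose and 0 fell, also adjusted over the list alone (median 1.29, camera adjusted p = 4.83e-05; adjusted p = 0.136 with an estimated correlation). RT1 genes are near-identical copies, so their values are uncertain. Of 9 tested interferon genes and receptors, 5 rose (Ifnb1, Ifnl1, Ifnl3, Ifngr1 and Ifngr2) and 2 fell (Ifnlr1 and Il10rb), also adjusted over the list alone (Ifngr2 lost its call as transcript rows, with a log2 fold change of 0.27 against 0.29 and an adjusted p of 0.0503, the highest of its alternatives; list median 0.29, camera adjusted p = 0.0372; adjusted p = 0.136 with an estimated correlation). Ifnb1, which encodes interferon beta, had 0 counts in INS-MOCK and 9.02 ± 1.22 CPM in INS-SMA, at least 70.0-fold higher.

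INS-MOCK replicate 1 held 252 counts of Rsad2 and 106 of Ifit1, against 28 and 35 and 8 and 4 in INS-MOCK replicates 2 and 3. Its ACTA2 count was 135, between the 103 and 167 of those libraries. Genes with at least 1 count numbered 15794 ± 75.1 in INS-MOCK and 17788 ± 333 in INS-SMA (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).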
